A study of Homo sapiens with 8 samples.

How the data were processed

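Poly(A) RNA was measured in 8 bulk libraries of human CD16-negative monocytes and of macrophages grown from them. Per the labels, monocytes were isolated from blood mononuclear cells of 2 healthy donors with a kit, cells were seeded on dishes in X-Vivo15 medium with 5% human serum, and 500 ng of DNase-treated total RNA per library went into poly(A) selection and a directional NEBNext Ultra II preparation with 10 PCR cycles. Each of the 4 groups held 1 library per donor, and the titles name the same 2 donors in every group, so the samples of a group are separate donors and those of a donor are related across groups. The labels do not say whether the monocyte group was cultured, and they do not say what TCM is.

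The deposited values are counts of fragments per gene, in 1 file per library and in a merged table. Per the file headers, the authors made the counts with featureCounts 2.0.1 over exons grouped by gene, for paired reads, with GENCODE release 40 and with neither a strand setting nor a setting for multiply mapped or multiply assigned reads. The authors' processing notes name STAR 2.7.10b, featureCounts 2.0.1, R 4.2.1, the GRCh38 genome and DESeq2 without a version. Since the counting was unstranded, fragments of genes that overlap on opposite strands could not be told apart and were left unassigned where they fell on exons of more than 1 gene. All 492352 values of the merged table were equal to those of the single files, which were used here. Of 286 named genes, 2 had at least 50% of their exon bases covered by exons of another gene, and 247 had under 10% covered. Reads of related genes (CCL3 and CCL4, CXCL1, CXCL2 and CXCL3, the FCGR genes, HSPA1A and HSPA1B, HBB and HBD) may not have been fully told apart.

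The files held 61544 genes. Before scaling, 1223 genes on chromosome Y, XIST, TSIX, immunoglobulin and T cell receptor segments, HLA-DRB3, HLA-DRB4 and HLA-DRB5 were left out, since they mark persons, which left 60321. Gene names came from a table of gene names for 39863 of them and biotypes from GENCODE 29 for 57137. Genes were kept by filterByExpr by group, which left 18466, and libraries were scaled with TMM factors between 0.8689 and 1.216. Counts were tested with the robust quasi-likelihood F test of edgeR 4.0.16 (with limma 3.58.1 in R 4.3.3), all 8 libraries in 1 fit with group means, and called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The 6 comparisons were each pair of the 4 groups. Besides adjustment over all genes, p-values were adjusted over the members of each gene list alone.

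The gene lists, the comparisons, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each comparison, the 6 largest rises and the 6 largest falls among protein-coding genes with a symbol, an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and the same sign in both donors. For each list it names up to 4 called members with the largest changes, the same sign in both donors and at least 5 CPM in the higher group, or else 2 members with the highest CPM as values. It adds 12 fixed genes (CD163, MRC1, CD80, CD86, CXCL10, CCL18, IL10, CD274, SPP1, TGFBI, S100A8 and CD14). The text gives a selection of these, and members named only because they were called in a short list or went against it were chosen after their values were seen.

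The 34 lists, with 587 members all found in the files, were interferon response, LPS and NF-kB inflammatory genes, M1 surface and costimulatory markers, IL-4 response, IL-10 response, TGF-beta response, tumour-associated macrophage markers, immune checkpoint and inhibitory receptors, proteases and inhibitors of matrix turnover, monocyte markers, lysosome, lipid handling, cholesterol biosynthesis, glycolysis, hypoxia response, nuclear encoded oxidative phosphorylation, mitochondrially encoded genes, MHC class II presentation, MHC class I presentation, tryptophan and arginine metabolism, iron handling, phagocytic and pattern recognition receptors, cell cycle, and immediate early and heat shock genes. Markers of other cells were lists for T cells, B cells, NK cells, platelets, erythroid cells, neutrophils, dendritic cells, non-classical monocytes, epithelial cells, and fibroblasts and endothelial cells. Some genes belong to several lists. The 587 members count such genes once per list, and calls of lists that share genes are not independent. Lists with at least 5 tested members were tested with camera, which asks whether the members rank apart from other genes, with a preset correlation of 0.01 and with one estimated from the data. Fry was run beside it, which asks whether the members move one way on balance without comparing them with other genes. In 24 of 198 list tests the median or mean of the members had another sign than the test, and 0 of these were called.

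Distances between groups were the square root of the mean over genes of the product of the log2 fold changes of the 2 donors, with log2 CPM at a prior count of 2, and the correlation of these fold changes over genes is given without a p. The counts of genes shared by the 3 comparisons with monocytes are given beside those of independent lists and of unchanged groups simulated against the same monocyte libraries. Intervals for folds against 1 to 3 counts are 95% counting intervals, and a fold against 0 counts was bounded with 3 counts over the group.

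Depth ran from 29732071 to 38807964 counts per library. Across genes with at least 20 counts over a group, the spread between the 2 donors, which holds differences between persons as well as counting noise, was on average above counting noise, with a chi-square per gene of 255.4 in monocytes, 157.5 in M1-like, 76.4 in M2-like and 68.67 in TAM-like macrophages. The biological coefficient of variation of the fit was 31.9% with 4 residual degrees of freedom, or 25.7% with 3 when the donor was a block. As a check of the pairing, the deviations of the libraries from their group means correlated within a donor with r between 0.213 and 0.421 for each pair of groups. Every SD is between 2 donors and is itself imprecise.

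The tests were tried on simulated counts with the spread of the data and 200 changed genes. In TAM-like against M2-like macrophages 1.4% of genes changed by 2-fold were recovered, 45.0% of those changed by 4-fold and 63.5% of those changed by 8-fold. In the other comparisons these were 0% to 7.7%, 42.4% to 51.7% and 63.2% to 76.4%. More genes than these 200 were called in the data, from 636 to 9490 per comparison. The threshold on p is less strict then, so these rates do not carry over to the data. Between 7 and 13 unchanged genes were called per comparison. A 4-fold change planted in the 22 interferon response genes was called in all 6 comparisons. Besides it, 1 other list was called in TAM-like macrophages against monocytes and 0 in the rest. Simulated genes were drawn independently of one another, so these list results do not test the preset correlation.

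Alternatives were relative log expression factors, upper quartile factors, library totals with no factors, no filter beyond 1 count, at least 1 CPM in 2 libraries, the donor as a block, a test against a log2 fold change of 1 (glmTreat), the merged table, only the 4 libraries of the 2 groups, DESeq2 1.42.0, limma voom and each library left out in turn. For lists these were an estimated correlation, fry, the donor as a block, relative log expression factors and each library left out. Upper quartile factors and no factors were also tried for lists and named genes, a choice made after seeing the data. Distances and correlations of donors were also computed with prior counts of 0.5 and 10, for genes with a mean of at least 10 CPM, and with relative log expression factors. With 2 libraries per group, no test for outlying libraries and no other splits of the libraries were run.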

Results

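Poly(A)-selected RNA was sequenced from CD16-negative monocytes of 2 healthy donors and from 3 kinds of macrophage grown from such monocytes in vitro. The 8 libraries formed 4 groups, each with 1 library per donor. The groups were monocytes, M1-like, M2-like and TAM-like macrophages, where TAM stands for tumour-associated macrophage. M1-like macrophages had GM-CSF for 5 days, interferon gamma for 2 days and lipopolysaccharide for the final 18 h. M2-like macrophages had M-CSF for 5 days, then IL-4 for 48 h. TAM-like macrophages had M-CSF, IL-4 and IL-10 for 7 days in medium with 20% TCM, with TGF-beta in the last 48 h. Total counts per library were 32218482 and 29732071 in monocytes, 38021768 and 35445331 in M1-like, 37250745 and 38807964 in M2-like, and 38007385 and 36887781 in TAM-like macrophages, for replicates 1 and 2. Levels are in CPM, the counts per 1e6 counts of the library total times its TMM scaling factor, as mean ± SD over the 2 donors unless a single library is named. Counting intervals and floors cover counting error only. A fold change against a group with 0 counts is a lower bound, taken against 3 counts over the group.

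Monocytes and M1-like macrophages lay well apart from the rest, while M2-like and TAM-like macrophages lay close to each other. The M2-like and TAM-like libraries of a donor correlated with Pearson r of 0.961 and 0.963, and the 2 monocyte libraries with 0.955. The first principal component of the 2000 most variable genes held 56.1% of the variance and set monocytes apart from the 3 kinds of macrophage, and the second held 30.2% and set M1-like macrophages apart from the rest. The distance between groups, free of the independent noise of each donor, was 0.835 on the log2 scale for TAM-like against M2-like macrophages. It was 1.48 for M1-like against M2-like and 1.56 for TAM-like against M1-like macrophages. Against monocytes it was 2.00 for M1-like, 1.97 for M2-like and 2.11 for TAM-like macrophages. Across genes, which are not independent replicates, the fold changes of the 2 donors correlated with Pearson r = 0.725 for TAM-like against M2-like macrophages and with r from 0.870 to 0.884 for the other 5 comparisons. Mitochondrially encoded genes took 3.23% of the counts of M1 replicate 1 and 0.943% of those of M1 replicate 2, against 3.30% to 5.60% in the 6 other libraries.

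**Figure D1:**
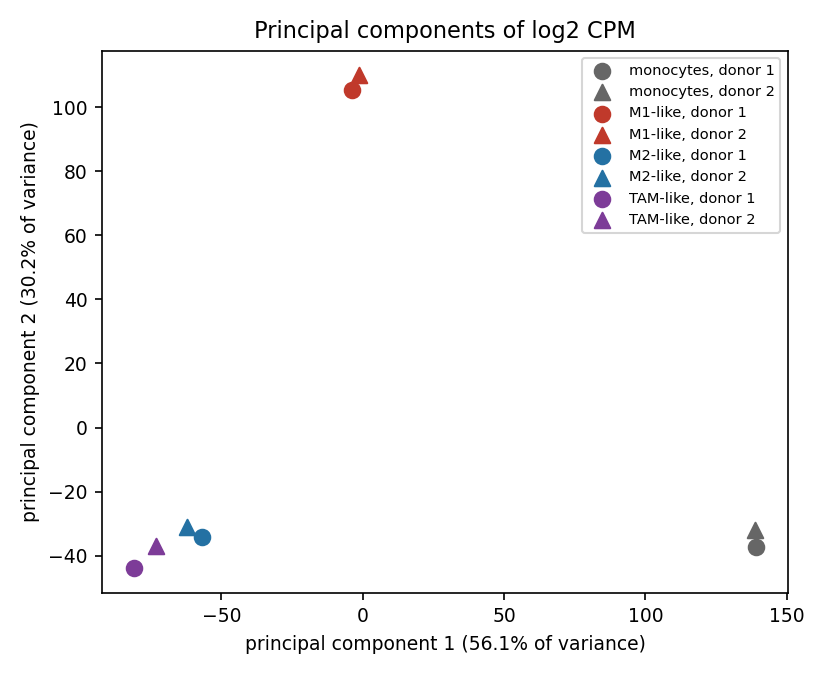
First and second principal components of log2 CPM over the 2000 most variable genes, with 1 point per library, coloured by group and marked by donor. The first component holds 56.1% of the variance and the second 30.2%, and the 2 donors of each group lie close together.

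M1-like and M2-like macrophages, the classical and the alternative polarisation, differed in interferon response, LPS and NF-kB inflammatory, MHC class I presentation and IL-4 response genes. CXCL9 (ENSG00000138755.6, GRCh38 chromosome 4, 76001275 to 76007509) and CXCL10 (ENSG00000169245.6, chromosome 4, 76021118 to 76023497), neighbouring chemokine genes induced by interferon, were among the largest rises. CXCL10 was at 905 ± 307 CPM in M1-like macrophages and had 0 counts in M2-like macrophages, at least 24922-fold higher (adjusted p = 0.000167). IL12B, a subunit of interleukin 12, was at least 14386-fold higher at 520 ± 239 CPM (adjusted p = 0.000372). In the other direction, the fatty acid binding protein gene FABP4 (ENSG00000170323.9, chromosome 8, 81478419 to 81483236) was 181-fold lower, at 10.8 ± 7.26 against 1957 ± 328 CPM (log2 fold change -7.50, SE 0.43, adjusted p = 0.000181).

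All 22 tested interferon response genes rose in M1-like macrophages, over all genes tested and when adjusted over the list alone (camera adjusted p = 1.98e-56). Their examples included CXCL9 at 4157 ± 996 CPM against 3 counts over the M2-like libraries, a ratio of 114073 (95% counting interval 39034 to 553151). IDO1, the tryptophan-degrading enzyme, was at 5162 ± 148 against 0.904 ± 0.955 CPM (log2 fold change 12.46, SE 0.84, adjusted p = 0.000582). Of 25 LPS and NF-kB inflammatory genes, 24 rose and 1 was not called, and 25 rose when adjusted over the list alone (camera adjusted p = 6.23e-38, adjusted p = 0.0417 with an estimated correlation). IL6 rose 1922-fold to 337 ± 67.5 CPM (adjusted p = 5.28e-05) and TNFAIP6 rose 2729-fold to 2492 ± 543 CPM (adjusted p = 0.000102). Of 15 M1 surface and costimulatory markers, 13 rose and 2 were not called, both over all genes and adjusted over the list alone (camera adjusted p = 6.43e-30). CCR7, the homing receptor for lymph nodes, rose 370-fold to 509 ± 69.0 CPM (adjusted p = 6.37e-05), and CD80 rose to 202 ± 9.57 from 0.709 ± 0.0308 CPM (log2 fold change 8.15, SE 0.67, adjusted p = 0.000614). Of 14 MHC class I presentation genes, 11 rose and 3 were not called, by either adjustment (camera adjusted p = 1.91e-12). The peptide transporter TAP1 rose from 140.5 ± 31.9 to 1558 ± 215 CPM (adjusted p = 0.00049).

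Of 29 IL-4 response genes, 22 fell in M1-like against M2-like macrophages, 2 rose and 5 were not called, with 23 lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.06e-12). F13A1, a chain of coagulation factor XIII, had 3 counts over the M1-like libraries against 21.6 ± 2.20 CPM in M2-like macrophages, a ratio of 496.5 (95% counting interval 169.9 to 2407.5, adjusted p = 0.000545). The mannose receptor MRC1 fell 16.3-fold, from 2646 ± 1300 to 162 ± 83.8 CPM (adjusted p = 0.00225). The 2 members that rose were the chemokines CCL17 and CCL23, named after their values were seen. Of 20 cell cycle genes, 11 fell, 1 rose and 8 were not called, with 13 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000544, adjusted p = 0.231 with an estimated correlation). MKI67, a proliferation marker, was at 2.55 ± 0.800 against 39.4 ± 7.05 CPM (log2 fold change -3.95, SE 0.44, adjusted p = 0.00141). Of 22 lipid handling genes, 8 fell and 3 rose, with 10 lower and 4 higher when adjusted over the list alone (camera adjusted p = 0.00108, adjusted p = 0.298 with an estimated correlation). With the donor as a block 10 were lower and 5 higher.

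MHC class II presentation genes were higher in M1-like macrophages for 7 of 10 members, by either adjustment, with none lower (camera adjusted p = 0.000291, adjusted p = 0.247 with an estimated correlation). HLA-DRA was at 3310 ± 481 against 869 ± 144 CPM (adjusted p = 0.00417). Of 20 immune checkpoint and inhibitory receptors, 11 rose and 2 fell, with 12 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.231 with an estimated correlation). CD274, the ligand PD-L1, was at 745 ± 162 against 77.0 ± 0.216 CPM (log2 fold change 3.27, SE 0.48, adjusted p = 0.00412). Of 18 IL-10 response genes, 10 rose and 4 fell, by either adjustment (camera adjusted p = 0.00143, adjusted p = 0.231 with an estimated correlation). Those that rose included the complement genes C1QA, C1QB and C1QC, with C1QB 49.6-fold higher at 1087 ± 304 CPM (adjusted p = 0.000221). Those that fell were MERTK, VSIG4, STAB1 and MSR1, receptors for dying cells, complement or modified lipoproteins. Tryptophan and arginine metabolism genes rose in 7 of 15 cases and fell in 3, TDO2, SLC7A1 and SLC7A2, by either adjustment (camera adjusted p = 0.00167, adjusted p = 0.231 with an estimated correlation). Hypoxia response genes rose in 6 of 16 cases and MXI1 fell, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00197, adjusted p = 0.513 with an estimated correlation). Glycolysis genes rose in 10 of 20 cases and fell in none, with 11 higher when adjusted over the list alone (camera adjusted p = 0.000806, adjusted p = 0.231 with an estimated correlation). Of 13 mitochondrially encoded genes, MT-ND4L fell and the list was lower by camera (adjusted p = 0.000974, adjusted p = 0.612 with an estimated correlation), with 0 called when adjusted over the list alone. The mitochondrial share of M1 replicate 2, 0.943%, was the lowest of the 8 libraries. With the donor as a block 9 members were called lower. The call of MT-ND4L ended without either monocyte library, M1 replicate 2, either M2-like library or TAM replicate 1, with an adjusted p of up to 0.147, without M2 replicate 1. Non-classical monocyte markers rose in 4 of 8 cases, by either adjustment (camera adjusted p = 0.0282, adjusted p = 0.231 with an estimated correlation), and all 9 summed to 750 and 663 CPM in the M1-like and 349 and 365 CPM in the M2-like libraries. All 3 tested erythroid genes rose, with HBB at 27.3 ± 12 CPM against 0 counts, at least 732-fold higher (adjusted p = 0.00324). Reads of HBB and its close paralog HBD could not be fully told apart. COL1A1, a collagen gene of the fibroblast and endothelial list, was at 112 ± 47.4 against 0.736 ± 0.393 CPM (adjusted p = 0.000254). COL1A2 rose as well (adjusted p = 0.0131), a call that ended without M1 replicate 2, M2 replicate 1 or M2 replicate 2 (adjusted p up to 0.0913, without M2 replicate 1), and COL1A2 and COL3A1 together had at most 6.68% of the COL1A1 counts in the M1-like libraries. Of the 10 tested members of that list 4 were higher and 3 lower, by either adjustment, and the list was not called (camera adjusted p = 0.774).

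In all, 2174 genes were higher and 2008 lower in M1-like than in M2-like macrophages, of 18466 tested, and each had the same sign in both donors. With upper quartile factors 1843 were higher and 2502 lower, so that the balance turned. With library totals and no scaling factors, 1669 were higher and 2542 lower, around a median of all genes of -0.22 on the log2 scale. No named gene that was called changed its direction. Among the 12 genes given in every comparison, S100A8 rose (adjusted p = 0.00136), and CD163 (adjusted p = 0.124), CD86 (adjusted p = 0.404), IL10 (adjusted p = 0.345) and TGFBI (adjusted p = 0.247) were not called. SPP1 was lower (adjusted p = 0.0175), CCL18 lower (adjusted p = 0.0444) and CD14 higher (adjusted p = 0.0491) in M1-like macrophages, and each call ended without M1 replicate 2 (adjusted p = 0.0999, 0.183 and 0.255), M2 replicate 1 or M2 replicate 2. The calls of SPP1 and CD14 also ended without M1 replicate 1, those of CCL18 and CD14 without either TAM-like library, and that of CCL18 without monocyte replicate 1. CD14 was not called with upper quartile factors or with no factors. The count of genes called was 2304 without M1 replicate 1, 1799 without M1 replicate 2, 1859 without M2 replicate 1 and 1771 without M2 replicate 2. Among the 104 named genes that were called, 76 stayed so in each of the 8 fits without 1 library.

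**Figure D2:**
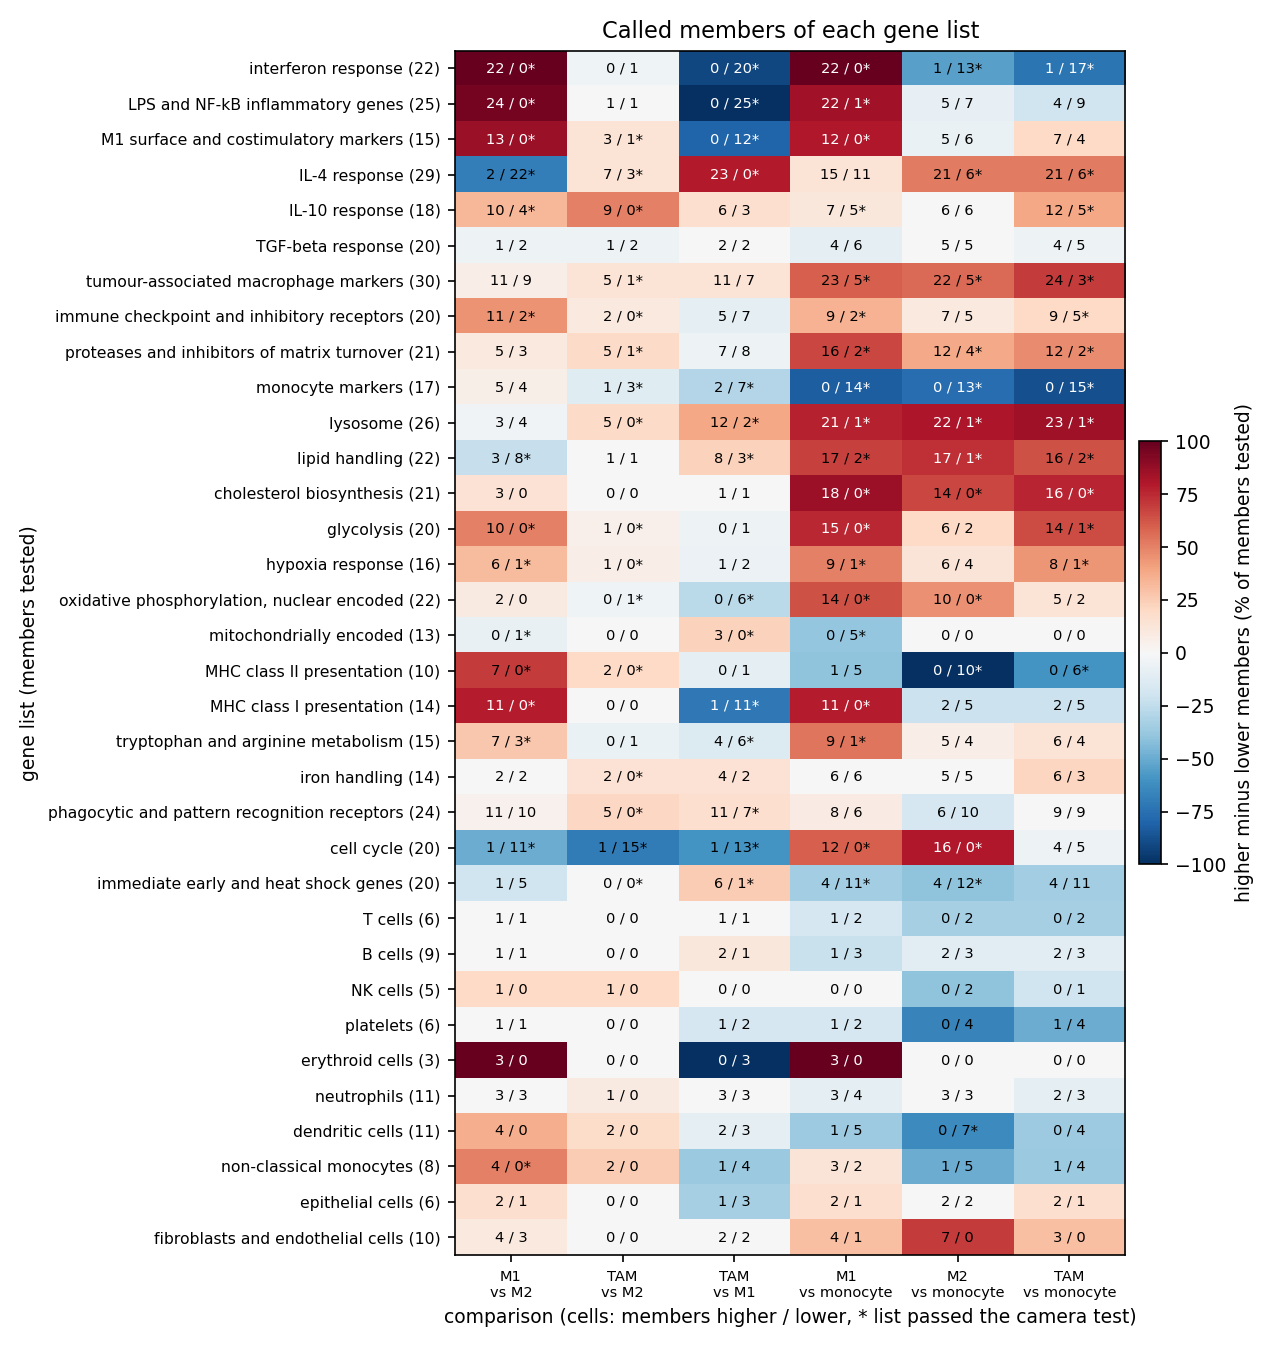
Members of each gene list (number tested in brackets) called higher / lower in each comparison, with colour showing the percent called higher minus the percent called lower, and an asterisk where camera's adjusted p with the preset correlation was under 0.05. All 22 interferon response genes were higher in M1-like than in M2-like macrophages, and 15 of 20 cell cycle genes were lower in TAM-like than in M2-like macrophages.

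TAM-like macrophages were compared with M2-like macrophages, which shared M-CSF and IL-4, to see what the longer IL-4 exposure with IL-10, 20% TCM medium and TGF-beta went with. As lists, IL-10 response and IL-4 response genes were higher in TAM-like macrophages (camera adjusted p = 8.91e-20 and 1.96e-08), and cell cycle genes were lower (1.71e-31). With an estimated correlation the camera adjusted p was 0.0314 for each of these lists, and 0.0389 for tumour-associated macrophage markers. The IL-10 response list was also higher in M1-like than in M2-like macrophages (camera adjusted p = 0.00143, or 0.231 with an estimated correlation). It was not called between TAM-like and M1-like macrophages (camera adjusted p = 0.118). In TAM-like against M2-like macrophages the largest rise was that of MUCL1 (ENSG00000172551.12, GRCh38 chromosome 12, 54830518 to 54896008), a small secreted mucin-like protein. It was at 507 ± 242 against 0.297 ± 0.348 CPM (1659-fold, log2 fold change 10.70, SE 0.79, adjusted p = 0.0034), while EPCAM and keratin counts together stayed at 0.217% of its counts or less. The cytokine receptor gene IL17RB rose 129-fold to 878 ± 199 CPM (log2 fold change 7.01, SE 0.32, adjusted p = 0.00108). The proliferation marker MKI67 was at 0.181 ± 0.128 against 39.4 ± 7.05 CPM, 213-fold lower (log2 fold change -7.74, SE 0.60, adjusted p = 0.00239).

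Of 18 IL-10 response genes, 9 rose, 0 fell and 9 were not called, with 13 higher when adjusted over the list alone (camera adjusted p = 8.91e-20). C1QB, a chain of the first complement component, rose 41.0-fold, from 21.9 ± 9.48 to 899 ± 92.4 CPM (adjusted p = 0.00239). The signalling inhibitor SOCS3 rose from 12.4 ± 6.04 to 406 ± 74.8 CPM (log2 fold change 5.03, SE 0.47, adjusted p = 0.00636). The haemoglobin scavenger receptor CD163 rose 9.47-fold, from 86.6 ± 26.0 to 820 ± 75.0 CPM (adjusted p = 0.00929). Of 29 IL-4 response genes, 7 rose, 3 fell and 19 were not called, with 9 higher and 5 lower when adjusted over the list alone (camera adjusted p = 1.96e-08). The chemokine CCL18 was at 8157 ± 3091 against 128 ± 23.9 CPM, 63.7-fold higher (adjusted p = 0.00797), and CCL13 rose to 300 ± 178 from 4.63 ± 2.42 CPM (adjusted p = 0.00517). The 3 members that fell, named after their values were seen, were the lipid antigen presenting genes CD1A, CD1B and CD1C. Of 30 tumour-associated macrophage markers, 5 rose (C1QB, C1QC, MMP12, CCL8 and CD163), MMP9 fell and 24 were not called, with 12 higher and 3 lower when adjusted over the list alone and 7 higher and 2 lower with the donor as a block (camera adjusted p = 4.5e-06). C1QB, C1QC and CD163 are also in the IL-10 response list, and MMP12 and MMP9 in that of proteases and inhibitors of matrix turnover. Without M2 replicate 1 or without M2 replicate 2 the calls of CD163 and CCL18 ended, with adjusted p of up to 0.0706 and 0.0591, both without M2 replicate 2.

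Of 20 cell cycle genes, 15 fell in TAM-like against M2-like macrophages, 1 rose and 4 were not called, with 16 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.71e-31). RRM2, a subunit of ribonucleotide reductase, was at 0.151 ± 0.128 against 16.7 ± 1.74 CPM (log2 fold change -6.76, SE 0.66, adjusted p = 0.00517). TOP2A, the topoisomerase of dividing cells, was at 0.257 ± 0.192 against 15.8 ± 1.76 CPM (adjusted p = 0.00685). MCM5, a part of the replicative helicase named after its values were seen, was the member that rose. With library totals and no factors, 16 cell cycle genes were called lower. Among the largest falls were PHGDH, the enzyme that opens serine synthesis, 37.4-fold lower (0.742 ± 0.195 against 27.9 ± 9.20 CPM, adjusted p = 0.00312). ME1, the cytosolic malic enzyme, was another (2.77 ± 0.0722 against 48.2 ± 3.69 CPM, adjusted p = 0.00108).

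Of 21 proteases and inhibitors of matrix turnover, 5 rose (MMP1, MMP7, MMP12, TIMP1 and ADAM19) and MMP9 fell, with 9 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.176 with an estimated correlation). MMP12, the macrophage elastase, rose 29.2-fold to 778 ± 45.6 CPM (adjusted p = 0.00435), and TIMP1, an inhibitor of such proteases, from 30.8 ± 2.42 to 648 ± 149 CPM (adjusted p = 0.00494). MMP9, a gelatinase, fell 37.0-fold from 812 ± 2.17 to 22.0 ± 1.35 CPM (log2 fold change -5.21, SE 0.28, adjusted p = 0.00108). Of 26 lysosome genes, 5 rose, among them CTSB, CTSL and CTSZ, and 0 fell, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00316, adjusted p = 0.29 with an estimated correlation). MHC class II presentation genes rose in 2 of 10 cases, HLA-DPA1 and HLA-DOA, and in 7 when adjusted over the list alone (camera adjusted p = 4.5e-06, adjusted p = 0.226 with an estimated correlation). Glycolysis genes were called in 1 of 20 cases, LDHA, which rose, and in 6 when adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.143 with an estimated correlation). Monocyte markers fell in 3 of 17 cases, among them FCN1, and S100A9 rose, with 5 lower and 2 higher when adjusted over the list alone and 4 lower and 2 higher with the donor as a block (camera adjusted p = 0.00237, adjusted p = 0.443 with an estimated correlation). FCN1, a pattern recognition lectin of monocytes, fell 58.5-fold to 0.302 ± 0.128 CPM (adjusted p = 0.00108). Without M2 replicate 2 the calls of CTSB (adjusted p = 0.272), CTSL (0.224), HLA-DPA1 (0.237), HLA-DOA (0.145) and S100A9 (0.13) ended, as they did without M2 replicate 1, TAM replicate 1 or TAM replicate 2. Leaving out any of the same 4 libraries ended those of CTSZ and LDHA, with adjusted p of up to 0.323 and 0.196. The calls of CTSB, CTSL, CTSZ, LDHA and HLA-DPA1 also ended without M1 replicate 1 and without M1 replicate 2.

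Another 7 lists were called with few of their members. Iron handling had 2 of 14 members higher (HAMP and CD163), or 5 higher and 1 lower when adjusted over the list alone and with the donor as a block (camera adjusted p = 0.00114, adjusted p = 0.122 with an estimated correlation). Immune checkpoint and inhibitory receptors had 2 of 20 higher (SIGLEC10 and LAIR1), or 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00237, adjusted p = 0.26 with an estimated correlation). Hypoxia response had 1 of 16 higher (P4HA2), or 3 when adjusted over the list alone and with the donor as a block (camera adjusted p = 0.000293, adjusted p = 0.382 with an estimated correlation). Nuclear encoded oxidative phosphorylation had 1 of 22 lower, COX5B, by either adjustment (camera adjusted p = 0.00316, adjusted p = 0.382 with an estimated correlation), and its adjusted p was 0.0702 without M2 replicate 1. Phagocytic and pattern recognition receptors had 5 of 24 higher (MARCO, FCGR1A, FCGR2A, FCGR2B and STAB1), or 6 higher and 4 lower when adjusted over the list alone and 6 higher and 2 lower with the donor as a block. That list's camera adjusted p = 0.0136 became adjusted p = 0.41 with an estimated correlation and 0.0821 without M2 replicate 2. M1 surface and costimulatory markers had 3 of 15 higher (FCGR1A, IL7R and IL2RA) and SLAMF7 lower, or 6 higher and 3 lower when adjusted over the list alone and 5 higher and 1 lower with the donor as a block (camera adjusted p = 0.0364, adjusted p = 0.244 with an estimated correlation). Its adjusted p was 0.101 without M2 replicate 1 and 0.0831 without TAM replicate 2. Immediate early and heat shock genes had 0 of 20 called (camera adjusted p = 0.0492, adjusted p = 0.703 with an estimated correlation). The list's adjusted p was 0.0518 with the donor as a block, 0.0528 with relative log expression factors, 0.0504 with no factors, 0.641 without M2 replicate 2 and 0.0833 without TAM replicate 2. Members named here that the rule for named genes had not picked were chosen after their values were seen. CD163, MARCO and STAB1 are also in the IL-10 response list, and FCGR1A is in both of the lists where it is named. Without M2 replicate 1, M2 replicate 2, TAM replicate 1 or TAM replicate 2 the calls of HAMP (adjusted p up to 0.12), LAIR1 (0.107), MARCO (0.106), COX5B (0.251), FCGR1A (0.224), IL7R (0.211) and SLAMF7 (0.33) ended. The calls of COX5B, FCGR1A, IL7R and SLAMF7 also ended without M1 replicate 1, and those of the last 3 without M1 replicate 2. The call of P4HA2 ended without M2 replicate 1, M2 replicate 2 or TAM replicate 1 (adjusted p up to 0.139), and that of FCGR2B without M2 replicate 1, M2 replicate 2 or TAM replicate 2 (0.127). For SIGLEC10 it ended without M2 replicate 1, TAM replicate 1 or TAM replicate 2 (0.0915), for STAB1 without M2 replicate 2 or TAM replicate 2 (0.0762), and for CD163 without M2 replicate 1 or M2 replicate 2 (0.0706).

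The remaining lists were not called between TAM-like and M2-like macrophages. For interferon response 0 of 22 members rose and 1 fell by either adjustment (camera adjusted p = 0.3). Of LPS and NF-kB inflammatory genes 1 of 25 rose and 1 fell, or 4 and 7 when adjusted over the list alone and 1 and 2 with the donor as a block (camera adjusted p = 0.433). Of TGF-beta response genes 1 of 20 rose and 2 fell by either adjustment (camera adjusted p = 0.471). Lipid handling had 1 of 22 members higher and 1 lower, or 2 and 3 when adjusted over the list alone and 1 and 2 with the donor as a block (camera adjusted p = 0.675). Tryptophan and arginine metabolism had 0 of 15 higher and 1 lower, or 1 and 1 when adjusted over the list alone and with the donor as a block (camera adjusted p = 0.461). Cholesterol biosynthesis, mitochondrially encoded and MHC class I presentation genes had 0 members called by either adjustment (camera adjusted p = 0.675, 0.675 and 0.935), with 1 cholesterol gene higher with the donor as a block. Among markers of other cells, 0 members were called for T cells (camera adjusted p = 0.971), B cells (0.18), platelets (0.433), epithelial cells (0.652) and the fibroblast and endothelial list (0.433), and for erythroid cells 0 of 3 tested, too few for a list test. Adjusted over the list alone, 1 B cell marker was higher, and 1 fibroblast or endothelial marker was higher and 3 lower, or 2 lower with the donor as a block. NK cells had 1 of 5 higher (camera adjusted p = 0.18), or 2 with the donor as a block, neutrophils 1 of 11 (0.675), dendritic cells 2 of 11 (0.46) and non-classical monocytes 2 of 8 (0.372). Adjusted over each list alone, 1, 2, 2 and 2 were higher and 0, 1, 2 and 0 lower.

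In all, 292 genes were higher and 344 lower in TAM-like than in M2-like macrophages, or 456 and 527 with the donor as a block, with 635 genes called by both fits. With library totals and no factors 210 were higher and 586 lower, around a median of all genes of -0.27 on the log2 scale. No named gene that was called changed its direction, while CTSB, CTSZ, FCGR1A and TGFBI were among those no longer called. Among the 12 fixed genes TGFBI rose (adjusted p = 0.035), a call that ended without each M1-like, M2-like or TAM-like library in turn (adjusted p up to 0.267, without M2 replicate 2). MRC1 (5209 ± 1227 against 2646 ± 1300 CPM, adjusted p = 0.391), CD274 (283 ± 57.2 against 77.0 ± 0.216 CPM, adjusted p = 0.0908) and SPP1 (adjusted p = 0.528) were not called. Neither were CD86 (adjusted p = 0.313), CD14 (adjusted p = 0.393), S100A8 (adjusted p = 0.244) and IL10 (adjusted p = 0.14), and CXCL10 had 0 counts in both groups. CD80 was not called (5.70 ± 3.30 against 0.709 ± 0.0308 CPM, adjusted p = 0.0636) except with the donor as a block (adjusted p = 0.0219). The count of 636 was 103 without M2 replicate 1, 162 without M2 replicate 2, 116 without TAM replicate 1, 123 without TAM replicate 2, 369 without M1 replicate 1, 372 without M1 replicate 2, 1563 without monocyte replicate 1 and 1571 without monocyte replicate 2. More genes were higher than lower with only the 4 libraries of these groups (1108 and 1008), without TAM replicate 1 (68 and 48) and without TAM replicate 2 (75 and 48). Of 55 named genes that were called, 19 stayed so in each of those 8 fits, among them MUCL1, IL17RB, CCL13, C1QB, C1QC, SOCS3, MMP12, TIMP1, MMP9, PHGDH, ME1, MKI67, RRM2, TOP2A and FCN1.

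**Figure D3:**
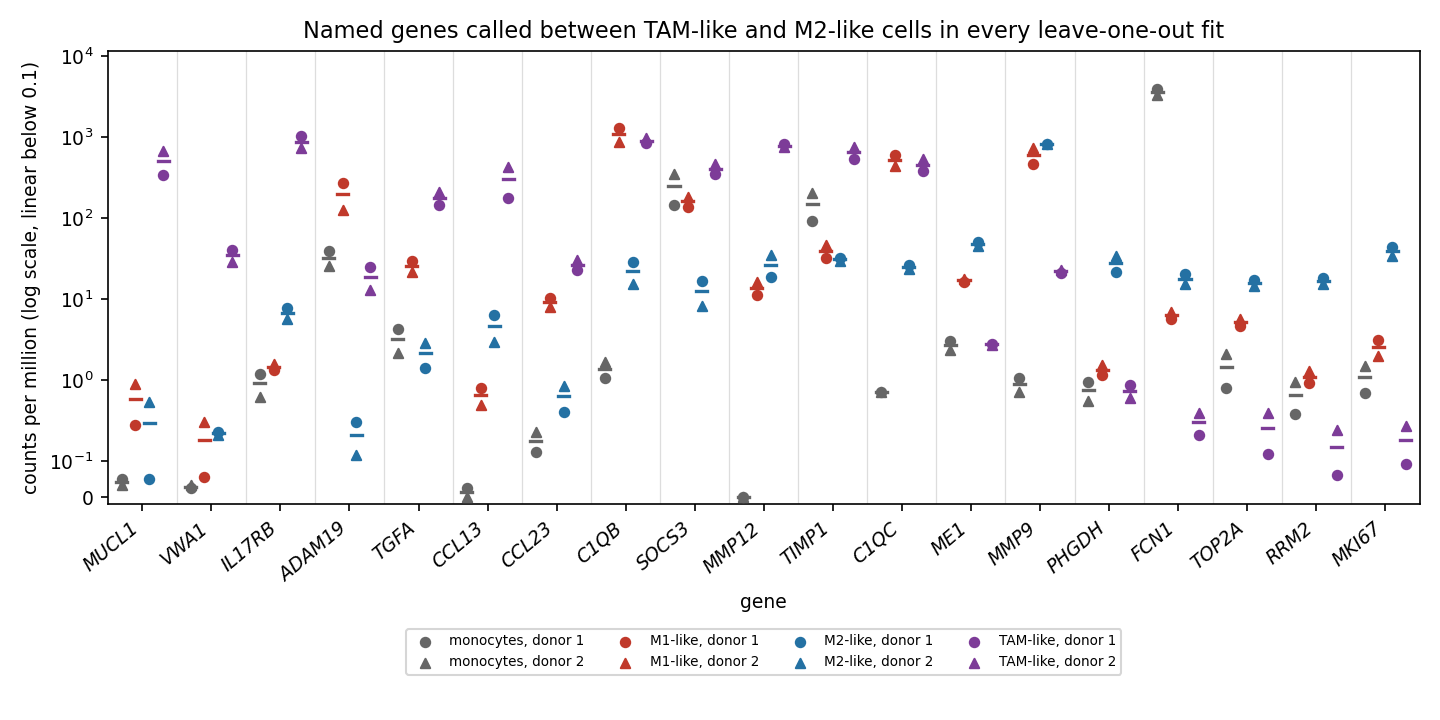
CPM in all 4 groups of the 19 named genes that were called between TAM-like and M2-like macrophages in each fit without 1 library. The vertical axis is linear near 0 and logarithmic above, with 1 point per library and a bar at the mean of the 2 donors. MKI67 lies at 39.4 CPM in M2-like and 0.181 CPM in TAM-like macrophages.

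TAM-like and M1-like macrophages differed in interferon response, LPS and NF-kB inflammatory, MHC class I presentation and IL-4 response genes. CXCL10 had 0 counts in TAM-like macrophages, at least 20169-fold lower (adjusted p = 0.000139), and TNFAIP6 was 7764-fold lower at 0.317 ± 0.277 CPM (adjusted p = 7.76e-05). IL17RB was 599.6-fold higher in TAM-like macrophages (log2 fold change 9.23, SE 0.34, adjusted p = 5.37e-05). The factor XIII chain gene F13A1 was at 682 ± 28.1 CPM against 0.0431 ± 0.0178 CPM, a ratio of 15610.3 (95% counting interval 5342 to 75696, adjusted p = 0.000103). FN1, which encodes fibronectin, was 147-fold higher (log2 fold change 7.20, SE 0.83, adjusted p = 0.00288).

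Interferon response genes fell in 20 of 22 cases, and in 22 when adjusted over the list alone (camera adjusted p = 8.47e-54). All 25 LPS and NF-kB inflammatory genes fell, by either adjustment (camera adjusted p = 8.67e-37), and so did 12 of 15 M1 surface and costimulatory markers, or 13 when adjusted over the list alone (camera adjusted p = 1.07e-23). MHC class I presentation genes fell in 11 of 14 cases and rose in 1, CALR, by either adjustment (camera adjusted p = 1.24e-11). IL-4 response genes rose in 23 of 29 cases and fell in none, with 24 higher and 1 lower when adjusted over the list alone and 23 and 1 with the donor as a block (camera adjusted p = 9.16e-21). MRC1 rose 32.1-fold (adjusted p = 0.000924), CCL18 259-fold (adjusted p = 0.000433) and CD163 18.2-fold (adjusted p = 0.000581). CD80 was lower (log2 fold change -5.15, SE 0.60, adjusted p = 0.00196), as were S100A8 (adjusted p = 0.00471) and CD14 (adjusted p = 0.00936, a call that ended without M1 replicate 2 or TAM replicate 1, at up to 0.0798). SPP1 (adjusted p = 0.00523) and TGFBI (adjusted p = 0.00255) were higher, while CD274 (adjusted p = 0.077), CD86 (adjusted p = 0.53) and IL10 (adjusted p = 0.222) were not called.

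Lysosome genes rose in 12 of 26 cases and fell in 2, with 13 and 3 when adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.301 with an estimated correlation). LIPA, the lysosomal acid lipase, rose with a log2 fold change of 2.99 (SE 0.25, adjusted p = 0.00036), and CTSL, a cathepsin, from 981 ± 18.8 to 7153 ± 756 CPM (adjusted p = 0.00401). Lipid handling genes rose in 8 of 22 cases and fell in 3, with 11 and 3 when adjusted over the list alone (camera adjusted p = 0.00275, adjusted p = 0.448 with an estimated correlation), FABP4 216-fold (adjusted p = 0.000135). Cell cycle genes fell in 13 of 20 cases and MCM5 rose, with 14 and 1 when adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.298 with an estimated correlation). Tryptophan and arginine metabolism genes fell in 6 of 15 cases and rose in 4, with 7 and 4 when adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.298 with an estimated correlation). GCH1, the first enzyme of tetrahydrobiopterin synthesis, was at 0.651 ± 0.451 against 589 ± 0.469 CPM (adjusted p = 5.37e-05). Mitochondrially encoded genes rose in 3 of 13 cases, or 9 when adjusted over the list alone and 10 with the donor as a block (camera adjusted p = 0.000787, adjusted p = 0.616 with an estimated correlation). The mitochondrial share was 0.943% in M1 replicate 2. The call of MCM5 ended without each M1-like, M2-like or TAM-like library in turn (adjusted p up to 0.259, without TAM replicate 1) and with no factors (0.0501).

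Of 20 immediate early and heat shock genes, 6 rose and 1 fell, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.616 with an estimated correlation). Nuclear encoded oxidative phosphorylation genes fell in 6 of 22 cases, or 7 when adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.5 with an estimated correlation). Their list's adjusted p was 0.0765 without TAM replicate 2. Phagocytic and pattern recognition receptors rose in 11 of 24 cases and fell in 7, or 12 and 8 when adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.5 with an estimated correlation). The call of that list ended with the donor as a block (adjusted p = 0.102), without monocyte replicate 1 (0.218), without monocyte replicate 2 (0.19) and without M1 replicate 2 (0.153). Monocyte markers fell in 7 of 17 cases and rose in 2, or 7 and 4 when adjusted over the list alone and with the donor as a block (camera adjusted p = 0.0479, adjusted p = 0.616 with an estimated correlation). Their call ended with the donor as a block (adjusted p = 0.125), with no scaling factors (0.0573), without monocyte replicate 1 (0.104), without monocyte replicate 2 (0.101) and without TAM replicate 2 (0.0799). Tumour-associated macrophage markers rose in 11 of 30 cases and fell in 7, or 13 and 10 when adjusted over the list alone, and were not called as a list (camera adjusted p = 0.248). Neither were IL-10 response genes (camera adjusted p = 0.118, adjusted p = 0.579 with an estimated correlation). Those rose in 6 of 18 cases and fell in 3, or 8 and 4 when adjusted over the list alone. In all, 2031 genes were higher and 2247 lower in TAM-like than in M1-like macrophages. The balance turned with upper quartile factors, at 2207 higher and 2096 lower, and with no factors 1724 were higher and 2332 lower. The count of 4278 was 2608 without M1 replicate 1, 2056 without M1 replicate 2, 1868 without TAM replicate 1 (936 higher and 932 lower) and 2081 without TAM replicate 2.

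**Figure D4:**
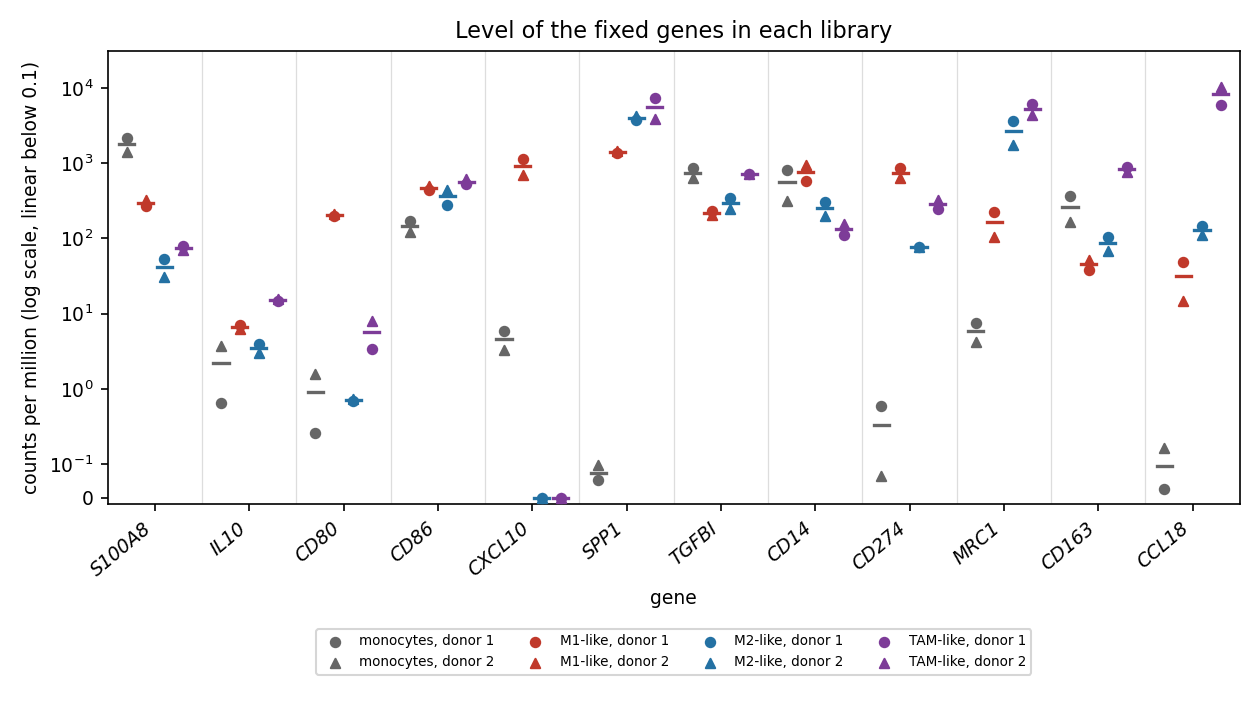
CPM of the 12 genes given in every comparison, in all 4 groups, with 1 point per library and a bar at the mean of the 2 donors. Its vertical axis is linear near 0 and logarithmic above. CXCL10 lies at 905 CPM in M1-like macrophages and has 0 counts in M2-like and TAM-like macrophages.

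Each kind of macrophage was also compared with monocytes, where lysosome genes rose as a list in all 3. FCN1 (ENSG00000085265.12, GRCh38 chromosome 9, 134903232 to 134917912) was at 3563 ± 436 CPM in monocytes and fell 564-fold in M1-like (adjusted p = 2.43e-05) and 11645-fold in TAM-like macrophages (adjusted p = 8.77e-06). SPP1 (ENSG00000118785.15, chromosome 4, 87975667 to 87983532), which encodes osteopontin, was at 0.0742 ± 0.0326 CPM in monocytes. It rose to 1405 ± 65.3 CPM in M1-like (adjusted p = 2.43e-05), 3964 ± 289 CPM in M2-like (adjusted p = 1.61e-05) and 5629 ± 2528 CPM in TAM-like macrophages (adjusted p = 1.08e-05). Monocyte markers fell in 14, 13 and 15 of 17 cases in M1-like, M2-like and TAM-like macrophages, or in 15 each when adjusted over the list alone, and rose in none, or in 1 in M2-like macrophages with the donor as a block (camera adjusted p = 2.82e-15, 2.07e-15 and 2.16e-17). Those 3 calls ended with an estimated correlation (adjusted p = 0.117, 0.12 and 0.132).

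Lysosome genes rose in 21 of 26 cases in M1-like (camera adjusted p = 3.01e-11), 22 in M2-like (1.05e-14) and 23 in TAM-like macrophages (1.05e-16), or 22, 24 and 23 when adjusted over the list alone, while TFEB, a regulator of lysosome genes, fell in each. Tumour-associated macrophage markers rose in 23, 22 and 24 of 30 cases and fell in 5, 5 and 3 (camera adjusted p = 3.05e-22, 4.01e-20 and 4.87e-24), with 23, 23 and 24 higher and 5, 7 and 5 lower when adjusted over the list alone. Lipid handling genes rose in 17, 17 and 16 of 22 cases, with 17, 18 and 16 when adjusted over the list alone, and fell in 2, 1 and 2 (camera adjusted p = 5.53e-10, 1.41e-15 and 3.04e-13). With an estimated correlation the call held for M2-like macrophages and ended for M1-like (adjusted p = 0.0627) and TAM-like macrophages (adjusted p = 0.052). APOE rose from 1.53 ± 1.55 CPM to 2382 ± 1290 CPM in M1-like (adjusted p = 0.000205), 4391 ± 126 CPM in M2-like (adjusted p = 0.000179) and 2405 ± 699 CPM in TAM-like macrophages (adjusted p = 0.000168). Cholesterol biosynthesis genes rose in 18, 14 and 16 of 21 cases, or 19, 15 and 16 when adjusted over the list alone, and fell in none (camera adjusted p = 1.71e-08, 4.76e-06 and 6.79e-06, and adjusted p = 0.301, 0.501 and 0.534 with an estimated correlation). Proteases and inhibitors of matrix turnover rose in 16, 12 and 12 of 21 cases and fell in 2, 4 and 2, with 5 lower in M2-like macrophages when adjusted over the list alone (camera adjusted p = 4.43e-08, 1.08e-05 and 2.28e-07). With an estimated correlation the call held in M1-like macrophages and ended in M2-like (adjusted p = 0.12) and TAM-like macrophages (adjusted p = 0.052).

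M1-like macrophages differed from monocytes by 22 of 22 interferon response genes, which rose by either adjustment (camera adjusted p = 6.93e-20), and by 12 of 15 M1 surface and costimulatory markers, which rose by either adjustment (camera adjusted p = 1.06e-14). LPS and NF-kB inflammatory genes rose in 22 of 25 cases and fell in 1, by either adjustment (camera adjusted p = 1.93e-16, adjusted p = 0.0809 with an estimated correlation). CD274 rose from 0.327 ± 0.370 to 745 ± 162 CPM (log2 fold change 11.06, SE 0.61, adjusted p = 5.66e-05), and IL12B was at least 12313-fold higher (adjusted p = 0.00016). CD163 fell 5.82-fold to 45.0 ± 9.47 CPM (adjusted p = 0.00199). Glycolysis genes rose in 15 of 20 cases, with 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.72e-05, adjusted p = 0.156 with an estimated correlation). MHC class I presentation genes rose in 11 of 14 cases, by either adjustment (camera adjusted p = 5.81e-05, adjusted p = 0.0774 with an estimated correlation). Of 13 mitochondrially encoded genes 5 fell, or 0 when adjusted over the list alone and 11 with the donor as a block (camera adjusted p = 0.0146, adjusted p = 0.626 with an estimated correlation). M1 replicate 2 had the mitochondrial share of 0.943%, and the list's call ended without monocyte replicate 1 (adjusted p = 0.068) or 2 (0.0662). IL10 was not called (adjusted p = 0.0731) except with the donor as a block (adjusted p = 0.0484).

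M2-like and TAM-like macrophages gained IL-4 response genes relative to monocytes. Of 29 IL-4 response genes, 21 rose and 6 fell in both (camera adjusted p = 1.06e-07 in M2-like and 6.21e-11 in TAM-like macrophages), with 7 lower in M2-like macrophages when adjusted over the list alone. In M1-like macrophages 15 rose and 11 fell, by either adjustment, and the list was not called (camera adjusted p = 0.221). The chemokine CCL22 (ENSG00000102962.5, chromosome 16, 57358783 to 57366189) rose from 0.465 ± 0.260 CPM by 15.45 on the log2 scale in M2-like (SE 0.45, adjusted p = 1.69e-05) and by 15.39 in TAM-like macrophages (SE 0.45, adjusted p = 1.38e-05). Interferon response genes fell in 13 and 17 of 22 cases and rose in 1, SOCS1, by either adjustment (camera adjusted p = 2.66e-05 and 1.61e-05, and adjusted p = 0.158 and 0.178 with an estimated correlation). MHC class II presentation genes fell in 10 of 10 cases in M2-like macrophages, by either adjustment (camera adjusted p = 1.55e-05, adjusted p = 0.252 with an estimated correlation). They fell in 6 in TAM-like macrophages, or 7 when adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.544 with an estimated correlation), where the call ended without TAM replicate 2 (adjusted p = 0.0668). CIITA, the master regulator of these genes, fell from 263 ± 13.8 to 31.1 ± 9.74 CPM in M2-like (adjusted p = 0.000264) and 78.2 ± 22.1 CPM in TAM-like macrophages (adjusted p = 0.00215). Cell cycle genes rose in 16 of 20 cases in M2-like macrophages, with 18 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.39e-08, adjusted p = 0.12 with an estimated correlation). They went both ways in TAM-like macrophages, with 4 higher and 5 lower, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.887). CD163 fell 3.03-fold in M2-like macrophages (adjusted p = 0.0124, and 0.0987 without M2 replicate 2). It rose 3.13-fold in TAM-like macrophages (adjusted p = 0.0104), where IL10 rose as well, from 2.18 ± 2.18 to 15.1 ± 0.876 CPM (adjusted p = 0.0108).

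Immediate early and heat shock genes summed to 24000 and 40500 CPM in the 2 monocyte libraries and to between 3020 and 5360 CPM in the 6 macrophage libraries. As a list they fell in M1-like macrophages, with 11 of 20 lower and 4 higher (camera adjusted p = 0.000948, adjusted p = 0.42 with an estimated correlation). The list fell in M2-like macrophages too, with 12 lower and 4 higher (camera adjusted p = 0.014, adjusted p = 0.66 with an estimated correlation, and 0.0624 without M2 replicate 2). In TAM-like macrophages 11 were lower and 4 higher and the list was not called (camera adjusted p = 0.0986). Adjusted over the list alone, 12 were lower and 4 higher in each of the 3 kinds of macrophage. FOS, an immediate early transcription factor, fell from 8597 ± 179 CPM in monocytes to 179 ± 31.6 CPM in M1-like macrophages (log2 fold change -5.59, SE 0.30, adjusted p = 5.19e-05).

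Further lists were called against monocytes. In M1-like macrophages immune checkpoint and inhibitory receptors rose in 9 of 20 cases and fell in 2, VSIR and LILRB3, by either adjustment (camera adjusted p = 5.81e-05, adjusted p = 0.136 with an estimated correlation). Tryptophan and arginine metabolism genes rose there in 9 of 15 cases and ARG1 fell, by either adjustment (camera adjusted p = 0.00178, adjusted p = 0.158 with an estimated correlation). Cell cycle genes rose there in 12 of 20 cases, or 13 when adjusted over the list alone (camera adjusted p = 0.00178, adjusted p = 0.256 with an estimated correlation). Immune checkpoint and inhibitory receptors rose in 9 cases and fell in 5 in TAM-like macrophages, by either adjustment (camera adjusted p = 0.00396, adjusted p = 0.263 with an estimated correlation), a call that ended without monocyte replicate 2 (adjusted p = 0.0743). IL-10 response genes rose in 12 of 18 cases and fell in 5 in TAM-like macrophages, by either adjustment (camera adjusted p = 4.25e-05, adjusted p = 0.215 with an estimated correlation). They rose in 7 and fell in 5 in M1-like macrophages, by either adjustment (camera adjusted p = 0.00669, adjusted p = 0.301 with an estimated correlation), where the call ended without monocyte replicate 1 (adjusted p = 0.125). Hypoxia response genes rose in 9 of 16 cases and fell in 1 in M1-like macrophages (camera adjusted p = 0.00178, adjusted p = 0.388 with an estimated correlation), and rose in 8 and fell in 1 in TAM-like macrophages (camera adjusted p = 0.0208, adjusted p = 0.58 with an estimated correlation), by either adjustment. Both calls ended without monocyte replicate 1 (adjusted p = 0.0773 and 0.259). Dendritic cell markers fell in 7 of 11 cases in M2-like macrophages, by either adjustment (camera adjusted p = 0.013, adjusted p = 0.411 with an estimated correlation). Glycolysis genes rose in 14 of 20 cases in TAM-like macrophages, or 15 when adjusted over the list alone, and PFKFB3 fell (camera adjusted p = 0.000317, adjusted p = 0.244 with an estimated correlation). Oxidative phosphorylation genes rose in 14 of 22 cases in M1-like macrophages, by either adjustment (camera adjusted p = 0.0137, adjusted p = 0.369 with an estimated correlation). They rose in 10 in M2-like macrophages, or 12 when adjusted over the list alone (camera adjusted p = 0.0474, adjusted p = 0.515 with an estimated correlation). The call in M2-like macrophages ended with the donor as a block (adjusted p = 0.0627), with upper quartile factors (0.0769), with no factors (0.0578) and without M2 replicate 1 (0.0987).

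Some lists that camera did not call against monocytes in the main fit were called with the donor as a block. Glycolysis genes, 6 higher and 2 lower in M2-like macrophages, had camera adjusted p = 0.075, or 0.0475 with the block. Dendritic cell markers, 1 higher and 5 lower in M1-like and 4 lower in TAM-like macrophages, had camera adjusted p = 0.137 and 0.0603, or 0.0494 and 0.0213 with the block, so that with it they were called in all 3 kinds of macrophage, as glycolysis genes were. Non-classical monocyte markers, 1 higher and 5 lower in M2-like macrophages, had camera adjusted p = 0.136, or 0.0357 with the block. Fibroblast and endothelial markers, 4 higher and 1 lower in M1-like and 7 higher in M2-like macrophages, had camera adjusted p = 0.0815 and 0.075, or 0.00839 and 0.0121 with the block, and in M1-like macrophages 0.0445 with upper quartile factors and 0.0368 with no factors. These counts of members were the same when adjusted over the list alone. Without the block and with an estimated correlation, camera adjusted p was 0.503 for glycolysis genes in M2-like and 0.42 for dendritic cell markers in M1-like macrophages. It was 0.481 for non-classical monocyte markers in M2-like macrophages, and 0.301 and 0.413 for fibroblast and endothelial markers in M1-like and M2-like macrophages. Fry called these lists without the block. Its adjusted p was 0.0106 for glycolysis genes in M2-like and 0.0253 for dendritic cell markers in M1-like macrophages. For non-classical monocyte markers in M2-like macrophages it was 0.0262. For fibroblast and endothelial markers it was 0.00546 in M1-like and 0.00814 in M2-like macrophages.

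Relative to monocytes, 4599 genes were higher and 4884 lower in M1-like, 4186 and 4890 in M2-like, and 4393 and 5097 in TAM-like macrophages. With upper quartile factors the counts were 3575 and 6156 in M1-like and 3610 and 6116 in TAM-like macrophages, and with no factors 3501 and 5855, and 3147 and 6457. The median of all genes lay between -0.05 and -0.12 on the log2 scale in these 3 comparisons and moved to between -0.19 and -0.46 with those factors. No named gene that was called changed its direction. The balance turned to more higher than lower genes with no filter beyond 1 count (5554 and 4561 in M1-like, 5167 and 4447 in M2-like, 5292 and 4649 in TAM-like macrophages) and with DESeq2 (4851 and 4449, 4498 and 4425, 4677 and 4610.0). It also turned without monocyte replicate 2 in M1-like (4622 and 4228) and M2-like macrophages (4140.0 and 4080.0), without M1 replicate 1 (3603 and 2873) and M1 replicate 2 (3578 and 2609), without M2 replicate 1 (2990.0 and 2248) and M2 replicate 2 (2905 and 2125), and without TAM replicate 1 (3013 and 2472) and TAM replicate 2 (3145 and 2663). In all 3 comparisons 2511 genes were higher and 3108 lower, against 248 and 357 for independent lists and 0 for unchanged groups simulated in 20 draws against the same monocyte libraries. The simulated groups were drawn around the observed monocyte means, so their 0 cannot show what the shared controls add. The 2 monocyte libraries could not be split, so part of the excess over either value may come from the shared controls. The count of genes lower in all 3 was 1882 without M1 replicate 1, 1822 without M1 replicate 2, 1587 without M2 replicate 1, 1509 without M2 replicate 2, 1705 without TAM replicate 1 and 1773 without TAM replicate 2. The count of genes changed was 6187 without M1 replicate 2 for M1-like macrophages, 5238 without M2 replicate 1 and 5030.0 without M2 replicate 2 for M2-like macrophages, and 5485 without TAM replicate 1 and 5808 without TAM replicate 2 for TAM-like macrophages.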

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

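No list call reversed with an estimated correlation, fry, the donor as a block, other scaling or a library left out, and no call of a named gene with other scaling, the block, DESeq2 or a library left out. For named genes and lists the filters, voom, the test against a log2 fold change of 1, the merged table and the 4-library fits were not run, and the tests of lists and named genes with upper quartile factors and with no factors were chosen only after the results were seen. The numbers of genes called stayed within 1.5 times of those reported with relative log expression factors, upper quartile factors, no factors, at least 1 CPM in 2 libraries, limma voom and the merged table. In TAM-like against M2-like macrophages the 636 genes called became 1616 with no filter beyond 1 count, 983 with the donor as a block, 2116 with only the 4 libraries of those groups and 1509 with DESeq2, and the cause was not tested beyond the changed set of libraries in the third. The balance of higher and lower genes turned under at least 2 settings in each comparison, as given beside the totals, and some uncalled lists changed direction with the donor as a block. Against a log2 fold change of 1, a stricter test by construction, 1769 genes were called in M1 vs M2, 197 in TAM vs M2, 1904 in TAM vs M1, 5144 in M1 vs monocyte, 4778 in M2 vs monocyte and 5278 in TAM vs monocyte, with 1132 shared higher and 1389 shared lower genes in the comparisons with monocytes. Leaving out each library in turn, where a lone library was assumed to vary like the other groups, gave 1771 to 6174 genes in M1 vs M2, 103 to 1571 in TAM vs M2, 1868 to 6126 in TAM vs M1, 6187 to 10778 in M1 vs monocyte, 5030 to 10417 in M2 vs monocyte, 5485 to 10632 in TAM vs monocyte, 1929 to 3394 shared higher and 1509 to 3526 shared lower genes. Those fits had fewer samples and, without a monocyte library, a spread shared by other libraries.

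Of 198 list tests 90 were called, and 26 with an estimated correlation, 98 with fry, 92 with the donor as a block, 89 with relative log expression factors, 90 with upper quartile factors, 88 with no factors and 88 to 98 without 1 library. The 26 calls that held with an estimated correlation had camera adjusted p between 0.00453 and 0.0436 there, far higher than with the preset correlation. The donor as a block gained 6 list calls and lost 4, and gained 11 and lost 1 of 676 results for named genes. The list calls that the block changed are given beside the results. Fry gained 21 list calls and lost 13. In TAM vs M2 fry ended the calls of M1 surface and costimulatory markers (adjusted p = 0.0652), immune checkpoint and inhibitory receptors (0.0652) and monocyte markers (0.158). It also ended those of hypoxia response (0.125), phagocytic and pattern recognition receptors (0.182) and immediate early and heat shock genes (0.407). The rest were lost in other comparisons, at 0.0544 to 0.0956. For named genes, DESeq2 gained 10 calls and lost 2, relative log expression factors lost 5, upper quartile factors gained 3 and lost 10, and no factors gained 3 and lost 16.

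In the order M1 vs M2, TAM vs M2, TAM vs M1, M1 vs monocyte, M2 vs monocyte and TAM vs monocyte, distances were 1.662, 0.923, 1.729, 2.26, 2.225 and 2.356 with a prior count of 0.5 and 1.234, 0.692, 1.31, 1.638, 1.613 and 1.738 with 10. The correlation of the 2 donors was 0.85, 0.642, 0.835, 0.86, 0.869 and 0.871 with a prior count of 0.5, and with 10 it was 0.904 in M1 vs M2, 0.795 in TAM vs M2, 0.91 in TAM vs M1 and 0.889 in TAM vs monocyte. For genes with a mean of at least 10 CPM it was 0.942, 0.867, 0.95, 0.89, 0.902 and 0.916, with distances of 0.717 in TAM vs M2 and 1.577 in TAM vs M1. A larger prior count shrinks folds of genes with few counts by construction. Depth set the bounds of folds against 0 counts.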

Other observations

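The genes in the first 2 paragraphs and the tests on lymphocyte markers, on CD68, on COL1A1 and on MUCL1 were chosen only after the results were seen.

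Some genes outside the lists, picked by their values and not tested as a group, also differed between TAM-like and M2-like macrophages. WNT5A, a ligand of the Wnt family, was at 14.2 ± 3.15 against 0.155 ± 0.147 CPM (log2 fold change 6.46, adjusted p = 0.00523) and reached 66.2 ± 19.3 CPM in M1-like macrophages. The growth factor gene PDGFB rose to 81.0 ± 10.5 from 5.53 ± 0.0460 CPM (log2 fold change 3.87, adjusted p = 0.00108), and the cytokine OSM to 16.5 ± 0.757 from 0.699 ± 0.488 CPM (adjusted p = 0.0236). ALDH1A2, an enzyme that makes retinoic acid, was at 754.5 ± 294.6 against 55.4 ± 29.9 CPM (log2 fold change 3.77, adjusted p = 0.00803). BPI, which binds lipopolysaccharide, fell to 0.0151 ± 0.0214 from 6.06 ± 1.07 CPM (adjusted p = 0.00147), and the pentraxin PTX3 to 3.41 ± 1.96 from 46.6 ± 20.0 CPM (adjusted p = 0.0235).

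Other genes picked this way have roles in serine and folate metabolism or hydrogen peroxide production, for which no list was tested. PHGDH was higher in M2-like macrophages than in monocytes (log2 fold change 5.20, adjusted p = 0.000144) and lower in both M1-like (-4.37, adjusted p = 0.000537) and TAM-like macrophages (-5.23, adjusted p = 0.00312) than in M2-like ones. In TAM-like against M2-like macrophages the mitochondrial folate enzymes ALDH1L2 (2.19 ± 0.284 against 22.6 ± 6.70 CPM, adjusted p = 0.00443) and MTHFD2 (adjusted p = 0.0472) and the stress gene CHAC1 (0.182 ± 0.0433 against 8.98 ± 3.27 CPM, adjusted p = 0.00825) fell, while PSPH (adjusted p = 0.995) and SHMT2 (adjusted p = 0.322) were not called. The oxidase DUOX1 rose to 114 ± 22.1 from 9.75 ± 0.0438 CPM (log2 fold change 3.55, adjusted p = 0.00108) and its maturation factor DUOXA1 to 52.9 ± 8.52 from 6.88 ± 0.112 CPM (adjusted p = 0.00569). Calls of these genes other than PHGDH were not tested without each library.

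Cell cycle genes were lower in TAM-like than in M2-like macrophages, and MCM5, at 92.6 and 69.0 CPM against 43.2 and 33.1 CPM, went the other way. Proliferating T or NK cells in the M2-like cultures were argued against. The 6 abundant lymphocyte transcripts tested summed to 0.79 CPM there, beside 39.4 ± 7.05 CPM of MKI67. Of these 6 only MS4A1 marks B cells, so B cells are less well covered. B cell markers summed to 29.1 and 52.8 CPM there, most of it CD22 (22.7 and 34.2 CPM). They summed to 52.7 and 60.3 CPM in the TAM-like libraries, where MKI67 was at 0.0909 and 0.272 CPM. The B cell marker CD79A was at 9.87 ± 8.02 CPM in M2-like against 3.35 ± 3.07 CPM in TAM-like macrophages (adjusted p = 0.558). Its log2 fold changes in TAM-like against M2-like macrophages were 0.389 in donor 1 and -3.66 in donor 2. With no factors 16 of 20 cell cycle genes were called lower, and 15 with relative log expression factors. Dropping the factors moved the median of all genes from 0.01 to -0.27 on the log2 scale, toward lower. That count could therefore hardly fall, and it does not decide on scaling. The factors of these libraries lay between 0.8689 and 1.094, far too close for the list's median log2 fold change of -3.24. The size of the difference thus argues against scaling. The difference in culture factors and in their timing between these groups stays open as an untested biological explanation, a hypothesis found on the same data.

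CD68, a macrophage marker, had low counts in every library, at 12 and 20.9 CPM in monocytes, 19.8 and 8.43 CPM in M1-like, 34.1 and 37.2 CPM in M2-like and 44.4 and 51.4 CPM in TAM-like macrophages. Exons of other genes covered 85.6% of its exon bases. Per kilobase of its 311 uncovered bases it lay at percentile 52 among the 25 other lysosome genes (134 CPM against a median of 131), and per kilobase of the whole exons at percentile 16 (19.3 against 111), so unassigned reads on shared exons may account for its low counts. For list members in general this cannot be told apart from chance differences in level, since 11 members at least 50% covered had 0.81 times the median CPM per kilobase of 451 members less than 10% covered (13.2 against 16.3). No biological explanation was tested.

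COL1A1 was at 78.3 and 145 CPM in the M1-like libraries and MUCL1 at 336 and 678 CPM in the TAM-like libraries. Fibroblasts in the M1-like cultures were argued against, since COL1A2, itself called higher there, and COL3A1 together had 6.68% of the COL1A1 counts in one library and 1.1% in the other, with 0 counts of COL3A1. Epithelial cells or their RNA in the TAM-like cultures were argued against, since EPCAM and 4 keratins together had 0.217% and 0.178% of the MUCL1 counts. Expression by the macrophages under the respective culture factors stays open and untested.

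Mitochondrially encoded genes took 0.943% of the counts of M1 replicate 2 and 3.23% of those of M1 replicate 1. Histone genes took 0.3995% and 1.3718% of the counts of the 2 monocyte libraries and 0.0498% to 0.1145% of those of the 6 macrophage libraries. In the M1-like libraries HBB was at 18.8 and 35.8 CPM, HBD at 6.54 and 7.63 CPM and ALAS2 at 1.0 and 1.34 CPM. T cell markers summed to between 3.82 and 21.9 CPM per library, NK cell markers to between 0.993 and 24.2 CPM, and B cell markers to between 8.54 and 60.3 CPM.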
